A study of Homo sapiens with 25 samples.

How the data were processed

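Single-nucleus ATAC-seq was carried out on undifferentiated H1 cells of 2 genotypes, wild type and YAP1 knockout, with 1 library each. Per the labels' protocols, frozen cells were thawed, their nuclei were permeabilized and tagmented in barcoded wells, and a further barcode was added after sorting, a scheme known as combinatorial indexing. The labels also describe 23 RNA-seq samples in 8 groups of 2 or 3 (wild type and knockout cells, undifferentiated or directed towards ectoderm, mesoderm and endoderm). Their values were not analysed here.

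The measurements came from 1 table of 311777 peaks that pools the nuclei of each library, with 1 row per peak. The submitters' processing notes name the genome build hg19 and, without a role for each, BWA 0.7.12, SAMtools 1.9, MACS2 2.1.2 and HOMER 4.9.1. The peak caller's settings, the filters on reads, nuclei or duplicates and the handling of reads that map to several places are not given in the sources used here. Per the file headers, each peak carries a position, an annotation with its nearest transcription start site (TSS) and gene, and the authors' comparison of both libraries. The authors deposited a log2 fold change and an average log2 CPM (count scaled to the library total) for each peak. They also deposited a p-value and an adjusted p-value. The last deposited column is a mark that was treated as a score, with 1 for a called peak and 0 otherwise. The mark was set exactly where the deposited adjusted p was under 0.05 and the fold was 2 or more in either direction (0 exceptions). Peaks so marked are termed called. The adjusted p equalled a Benjamini-Hochberg adjustment over all peaks.

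Which genotype is the numerator of the deposited fold is not given in the sources used here. It was not inferred from the values. The libraries are therefore termed the numerator library and the denominator library, and a positive fold is a higher value in the numerator library.

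The planned analysis allowed for counts, and the table gave none. The log2 fold and the average log2 CPM of each peak were jointly matched to whole counts in each library, with a prior count of 0.125 in the fold and of 2 in the average. All 311777 peaks matched within 1e-06 on the log2 scale, and the recovered counts summed exactly to the library totals that the match required: 42383055 in the numerator library and 27296422 in the denominator library. These totals include mitochondrial counts, and no further scaling factor was needed. The deposited p-values were matched within 1% for 99.97% of 50950 distinct rows by a two-sided exact negative binomial test with a coefficient of variation fixed at 0.1. That value is an assumption of the test and not a spread measured between replicates. A p-value of this kind compares 2 libraries, not 2 genotypes. The same test was recomputed only to count calls under other scalings and assumed spreads. The authors' p-values are given as theirs.

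Per-peak ratios were log2 of the numerator count plus 1 over the denominator count plus 1, each divided by its library total. A minimum of 20 counts over both libraries and chromosomes 1 to 22 and X left 305857 peaks. Because the libraries differ in depth, an equal pseudocount pulls ratios of low peaks slightly downwards. Intervals are 95% exact (Clopper-Pearson) intervals of the ratio of 2 counts. They cover counting error only: reads without molecular identifiers are not independent molecules, and neither culture nor library preparation was repeated. Where a library had 0 counts, the bound on the fold was computed against a floor of 3 counts in that library. The expected effect of counting error on all peaks was drawn binomially from each peak's combined count at equal rates.

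Gene values summed the counts of the peaks whose nearest gene it was, within 50 kb of the TSS, and separately within 1 kb (promoter). The median of each of 18 gene lists was placed among the medians of 10000 random lists of the same size, drawn with replacement from the other genes and matched on deciles of the depth-scaled count. A list was said to lie outside the random lists where its percentile was below 2.5 or above 97.5. The interval of a list's median came from Poisson resampling of its counts. Gene lists, the size criteria and the rule for named genes were fixed before the data were examined. The lists were YAP/TEAD targets, Hippo pathway components, pluripotency, NODAL and activin signaling, WNT signaling, BMP signaling, primitive streak and mesoderm, endoderm, neural ectoderm, surface ectoderm and neural crest, trophoblast and amnion, HOX genes, cytoskeleton and matrix, blood and immune cells, fibroblasts, housekeeping, cell cycle, and apoptosis and p53. The rule takes the 8 highest and 8 lowest peaks with a deposited p under 0.05, at most 1 per gene; the 6 highest and 6 lowest such peaks within 1 kb of a TSS; the 2 highest and 2 lowest genes of each list; and a set named in advance (YAP1, WWTR1, CYR61, CTGF, ANKRD1, NODAL, LEFTY1, POU5F1, NANOG, SOX2, T, EOMES, SOX17, PAX6, WNT3 and CDX2). Genes named outside this rule were chosen after their values were seen.

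Runs of neighbouring peaks that differ together, repeat subfamilies, zinc finger genes, the YAP1 locus without its highest peak and the calls of gene lists under other scalings were examined after the data were seen. A run is a stretch of at least 8 peaks in which the running median of 15 peaks lies at or beyond 1.5 on the log2 scale. Tests of the chromosome 9 run left out its first and last 15 peaks; they replaced a test of the whole run that was written before its values were known. Repeat names came from the deposited annotation; subfamilies with at least 60 peaks were compared with 1000 random sets of peaks matched on height in 20 bins.

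The steps were tested on simulated data. For 311459 simulated peaks with Poisson counts at the real mean rates, of which 200 were changed, all among the better-covered peaks, counts were recovered for 100% of peaks. The test called 88% of peaks simulated at a fold of 0.25, 100% of those at 4, 18% of those at 0.5 and 30% of those at 2. Of 100 random lists of 25 genes, built from the permuted gene ratios, 83% lay below 2.5% of random lists when lowered by 0.25 on the log2 scale, and 5% of unchanged lists lay outside.

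The alternatives tried were other scalings (median of ratios, TMM, promoter totals, totals without mitochondrial counts), other filters and pseudocounts, other fold and p thresholds, other distances to the TSS, the mean in place of the median, larger assumed coefficients of variation, and a correction for peak height and class. A share of peaks with the TEAD motif was planned but needs a genome sequence of the same build, which was not used here. Y-linked genes were left out. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.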

Results

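Chromatin accessibility was compared between undifferentiated H1 cells, an established human embryonic stem cell line, and H1 cells with a knockout of YAP1, the transcriptional coactivator at the end of the Hippo pathway. The comparison asks which genomic regions differ in accessibility between the genotypes before differentiation starts. Single-nucleus ATAC-seq, which reads where a transposase can insert into open DNA, gave 1 pooled library per genotype and 311777 peaks on hg19 in the authors' deposited table. The numerator library of the deposited fold held 42383055 counts in peaks and the denominator library 27296422, with a median of 38 and 27 counts per peak. Which genotype is the numerator of the deposited fold is not given in the sources used here, so every direction below is stated as numerator over denominator. There was no replicate, so no difference has a replicate check, and intervals cover counting error only. The 23 RNA-seq samples that the labels describe were not analysed here.

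YAP1 itself was accessible in both libraries. In the authors' deposited table it had 25 peaks between 101956815 and 102084254 on chromosome 11, and 0 of them had an adjusted p under 0.05, against 4.22% of all peaks on chromosomes 1 to 22 and X. Summed over these peaks, 4489 numerator counts stood against 2533 denominator counts, a log2 ratio of 0.19 (95% interval 0.12 to 0.26). The peak over exon 1 and the TSS (chromosome 11, 101980675 to 101982682) held 3123 and 1634 of these counts. The other 24 peaks, 18 of them with a negative fold, summed to a log2 ratio of -0.03 (interval -0.15 to 0.09). Accessibility of a gene with a small edit need not differ, so these values do not check the genotype labels. The paralog WWTR1, which encodes TAZ, had 1 called peak, 3.8 kb upstream of its TSS (chromosome 3, 149424653 to 149425138), with a log2 fold of 1.56 (interval 1.02 to 2.14) and an adjusted p of 0.000312 in the authors' deposited table. The 24 Hippo pathway components had a median log2 ratio of 0.21, at percentile 26.8 of matched random lists. Within this list TEAD2, which encodes a DNA-binding partner of YAP1, had the highest value (0.82, interval 0.59 to 1.06), followed by NF2, an upstream activator of the kinase cascade (0.56, interval 0.43 to 0.68). VGLL3 (-0.18) and PTPN14 (-0.08) had the lowest values.

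Genes that YAP1 and TEAD factors are known to activate stood apart from other genes. The 25 YAP/TEAD targets had a median log2 ratio of 0.00 (interval -0.03 to 0.08) within 50 kb of their TSS, while the median over 24280 genes was 0.27. This median lay below all 10000 matched random lists, whose central 95% ran from 0.14 to 0.36, and 21 of the 25 genes lay below the random median. In the authors' deposited table at least 1 called peak with a negative fold lay near 14 of the 25 genes, against a median of 4 in random lists, and 1 gene, ARHGEF17, had a called peak with a positive fold. With promoter totals 18 genes had a negative call, against a random median of 9. At a coefficient of variation of 0.2 there were 4 against 1 (percentile 98.5), and at 0.4 there were 0 against 0. Among peaks between 1 and 50 kb from the TSS of these genes, 17 of 224 (7.59%) were called with a negative fold and 1 with a positive fold in the authors' deposited table, against 2.51% and 1.18% of all peaks at that distance. Within 1 kb, 2 of 29 (6.90%) were called with a negative fold and 0 with a positive fold, against 0.62% and 1.41% of all such peaks. Within 1 kb of the TSS the median over 23 measured genes was 0.26, at percentile 8.07, inside the random lists. The mean over the same genes, 0.08, was at percentile 0.11, but the ANKRD1 promoter, at a log2 ratio of -2.69, pulls this mean down. The promoter mean of the cytoskeleton and matrix list was also low, at percentile 1.21.

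ANKRD1, a cardiac ankyrin repeat gene widely used as a readout of YAP activity, had the lowest value of the list, -1.05 (interval -1.19 to -0.91; 747 against 994 counts). Its promoter peak (chromosome 10, 92680914 to 92681176) had a log2 fold of -2.73 (interval -3.42 to -2.09) and an adjusted p of 4.9e-11 in the authors' deposited table. An intergenic peak about 10 kb upstream (92690929 to 92691135) had 15 against 144 counts, a log2 fold of -3.88 and an adjusted p of 8.0e-21 in the authors' deposited table. CYR61, now named CCN1 and encoding a secreted matrix protein, had a value of -0.39 (interval -0.47 to -0.31). Its promoter peak was at 0.00 (interval -0.11 to 0.11). That is percentile 10.8 among gene promoters, whose median was 0.37. An intergenic peak 26.7 kb downstream (chromosome 1, 86072868 to 86073461) held 200 against 578 counts. The log2 fold there was -2.17, with an adjusted p of 7.6e-16 in the authors' deposited table. CTGF, now CCN2 and a relative of CYR61, had a value of -0.32 (interval -0.39 to -0.26) and 1 called peak 1.8 kb upstream (chromosome 6, 132274214 to 132274384), at -1.16 in the authors' deposited table. CRIM1, a transmembrane regulator of growth factors, was at -0.51 with 2 called negative peaks in the authors' deposited table. FJX1 (0.36) and ARHGEF17 (0.33) had the highest values of the list.

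**Figure D1:**
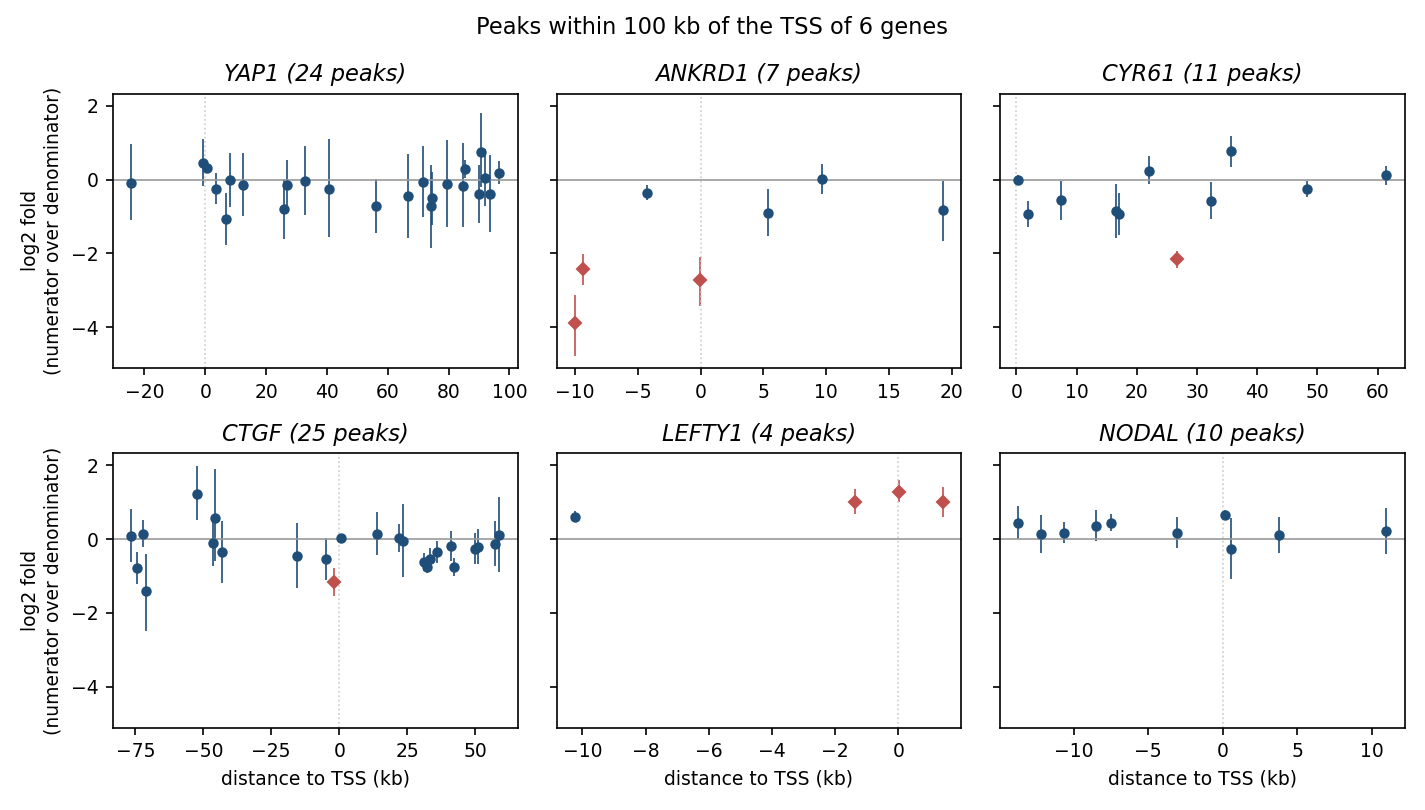
Deposited log2 fold (y axis, numerator over denominator) of each peak within 100 kb of the TSS of 6 genes, against its distance to the TSS in kb (x axis). Bars are 95% counting intervals, red diamonds are peaks called in the authors' deposited table and blue circles are other peaks; ANKRD1 has 3 called negative peaks, CYR61 and CTGF have 1 each, LEFTY1 has 3 called positive peaks, and YAP1 and NODAL have 0.

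**Figure D2:**
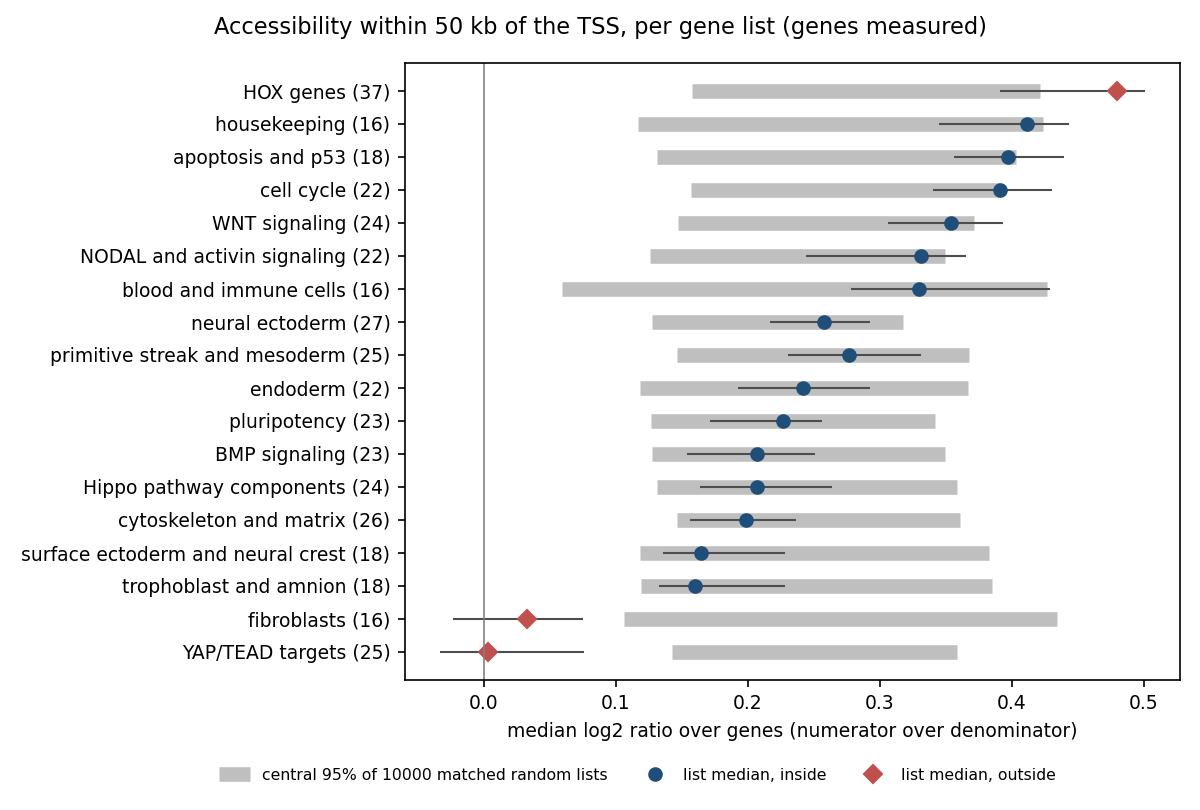
Median log2 ratio (x axis, numerator over denominator) over the measured genes of each of 18 lists, with the number of genes in brackets. Horizontal lines are counting intervals and grey bars the central 95% of 10000 matched random lists; the YAP/TEAD targets (0.00) and fibroblast markers (0.03) lie below their bars and the HOX genes (0.48) above theirs.

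Genes of the NODAL and activin pathway included several with higher values in the numerator library. The 22 genes had a median of 0.33, at percentile 95.1, inside the random lists. In the authors' deposited table, however, 6 of them had a called peak with a positive fold, against a median of 2 in random lists (percentile 99.7), and 4 had one with a negative fold, against a median of 4. The positive calls depended on the way of calling: 3 genes had one with totals without mitochondrial counts (percentile 94.5) and 2 with promoter totals (percentile 94.0). There were 6 with median of ratios (percentile 99.4) and with TMM (percentile 99.5). With the median fold of peaks of like height and class taken off there were 5 (percentile 98.6). At a coefficient of variation of 0.2 there were 0, but the random median was 0 too (percentile 42.3), so that setting cannot show an excess lost. LEFTY2 (0.86, interval 0.75 to 0.98) and LEFTY1 (0.80, interval 0.69 to 0.91), feedback inhibitors of NODAL that neighbour each other on chromosome 1, had the highest values. The LEFTY1 promoter peak (226076599 to 226077060) had 459 against 121 counts, a log2 fold of 1.29 and an adjusted p of 4.8e-05 in the authors' deposited table. Of the 3 called LEFTY1 peaks, 1 was called with totals without mitochondrial counts and 0 with promoter totals. With the median fold of peaks of like height and class taken off 0 were called, as at a coefficient of variation of 0.2. NODAL itself was at 0.47 (interval 0.38 to 0.56). Its TSS peak, at 0.66, had an adjusted p of 0.0522 in the authors' deposited table and was not called. TDGF1, the NODAL coreceptor, was at -0.29 (interval -0.41 to -0.16) and CER1, a secreted NODAL antagonist, at -0.11 (interval -0.28 to 0.06).

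The 23 measured pluripotency genes had a median of 0.23, at percentile 46.4. POU5F1 (0.56, interval 0.44 to 0.68), SOX2 (0.27, interval 0.21 to 0.33) and NANOG (0.23, interval 0.06 to 0.39), the core factors of the pluripotent state, had 0 called peaks within 50 kb in the authors' deposited table. DNMT3B, a de novo DNA methyltransferase abundant in embryonic stem cells, had the highest value (0.76, interval 0.67 to 0.85) with 2 called positive peaks, and FGF2 the lowest (-0.35, interval -0.43 to -0.28) with 1 called negative peak in the authors' deposited table. The promoters of this list were at percentile 3.39.

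The medians of the lineage lists lay inside the random lists before differentiation. The primitive streak and mesoderm list was at percentile 63.3 and the endoderm list at 48.6. In the authors' deposited table, however, 0 genes of the streak and mesoderm list had a called peak with a negative fold, against a median of 4 in random lists (percentile 0.42), but 3 had one with totals without mitochondrial counts (percentile 9.22) and 7 with promoter totals (percentile 22.3). The neural ectoderm list was at 77.8, the surface ectoderm and neural crest list at 10.7 and the trophoblast and amnion list at 9.01. Within the mesoderm list, MIXL1, an early primitive streak gene, was at 0.78 (interval 0.62 to 0.93) with 2 called positive peaks in the authors' deposited table, MEOX1 at 0.58, MSGN1 at -0.20 and TWIST1 at 0.02. The streak factors T (0.03, interval -0.06 to 0.12) and EOMES (0.15, interval 0.09 to 0.21) had 0 called peaks within 50 kb. SOX17, an endoderm factor, was at 0.20 and had 1 called peak 35 kb upstream, at -3.13 in the authors' deposited table (5 against 29 counts). PAX6, a neural factor, was at 0.12 and CDX2, a trophoblast and posterior factor, at 0.29, each with 0 called peaks. In the trophoblast and amnion list VTCN1 was lowest, at -0.94 (interval -1.24 to -0.65), followed by ENPEP at -0.34, with KRT7 (0.39) and GATA2 (0.36) highest. Of the endoderm genes, AFP (-0.47) and HNF4A (-0.24) were lowest and FOXA3 (0.61) was highest. Neural genes ran from MAP2 (-0.32) and SOX3 (-0.05) to PAX7 (0.54) and POU3F1 (0.62), and surface ectoderm and neural crest genes from KRT5 (-0.21) and TP63 (-0.13) to SOX10 (0.47) and DLX3 (0.50).

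The WNT list was at percentile 94.8, with WNT3, which induces the primitive streak, at 0.63 (interval 0.55 to 0.73) and NOTUM, a secreted WNT inhibitor, at 0.78. LGR5 (-0.04) and FZD7 (-0.01) were the lowest of that list. The BMP list was at percentile 29.3, with ID1, a BMP target, at 0.65, SMAD6 at 0.52, GREM1 at -0.09 and BMP5 at -0.44. The 37 measured HOX genes had a median of 0.48, at percentile 99.9, and 32 of them lay above the random median of 0.30. HOXC10 (1.19, interval 0.50 to 2.06, from 70 against 19 counts) and HOXC5 (0.77) were highest, and HOXD3 was at 0.21. HOX genes share clusters, so their values are not independent of each other. Their promoters were at percentile 79.7.

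Markers of other cell types and general lists were measured in the same way. The 16 fibroblast markers had a median of 0.03, at percentile 0.34, and share 0 genes with the YAP/TEAD targets. With the median fold of peaks of like height and class taken off, their excess over random lists went from -0.24 to -0.15 (percentile 2.53, at the bound of 2.5), and with peaks over 1 kb from the TSS to -0.17 (percentile 5.89). TWIST2 (-0.82, interval -0.96 to -0.67) and PDGFRB (-0.50) were lowest, TWIST2 beside a run of 9 low peaks on chromosome 2, and COL1A1 (0.40) and THY1 (0.44) were highest. The cytoskeleton and matrix list was at percentile 16.3 with COL4A1 at -0.52, TPM1 at -0.36, ITGA5 at 0.43 and ACTG1 at 0.59. The blood and immune list was at 80.5, from PTPRC (-0.37) and CD4 (-0.05) to CD14 (0.77) and CD3D (1.07). The housekeeping list was at percentile 96.3, the cell cycle list at 97.4 and the apoptosis and p53 list at 96.8. Each of these 3 medians lay inside the random lists. Their highest genes were POLR2A (0.75) and TBP (0.56), AURKB (0.73) and TOP2A (0.60), and BCL2L1 (0.85) and BAX (0.74). Their lowest were EEF1A1 (0.11) and PGK1 (0.15), CDKN2B (-0.08) and CDKN2A (0.03), and FAS (-0.06) and BCL2 (0.13). The promoters of the fibroblast markers were at percentile 1.41. Promoter medians of the remaining lists lay between percentiles 6.47 (cytoskeleton and matrix) and 96.2 (WNT).

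Over the 305857 peaks with at least 20 counts, the median log2 ratio was -0.05, with quartiles of -0.45 and 0.32. A ratio of at least 2-fold was seen at 7957 peaks (2.60%) in the higher direction and at 21021 peaks (6.87%) in the lower direction, while counting error alone gave 3391 and 2858. The authors' deposited table called 10683 peaks, 2462 with a positive and 8221 (77.0%) with a negative fold. The unadjusted p was under 0.05 for 50424 peaks in the authors' deposited table. The authors' deposited p-values rest on an assumed coefficient of variation of 0.1. With 0.2 in its place the same test called 276 positive and 1706 negative peaks, and with 0.4 it called 1 and 13. The totals include mitochondrial counts; without these all folds shifted by -0.15 and the calls were 1448 positive (10.7%) and 12079 negative. Scaled to promoter totals, folds shifted by -0.36 and the calls were 823 positive (3.32%) and 23987 negative. Under that scaling every positive gene value below the shift of 0.36 in size, YAP1 included, changed sign, and negative values stayed negative.

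The fold depended on the height of a peak and on its place in the genome. Its median was -0.15 for peaks with a log2 CPM between -1 and 0 and 0.37 for those between 4 and 5. Promoter-TSS peaks had a median fold of 0.38, exonic peaks 0.31, intronic peaks -0.05 and intergenic peaks -0.09. Promoter-TSS peaks made up 3.44% of the 2-fold higher peaks and 0.73% of the 2-fold lower peaks, against 1.98% and 1.54% of peaks of matched height. Over all heights they were 4.25% of peaks, so the share among the higher peaks was below the background there and above it at matched height. Exonic peaks made up 6.43% of the higher and 0.86% of the lower peaks, against 1.84% and 1.74% at matched height. Intergenic peaks were 54.3% of the lower peaks, against 50.6% at matched height. The libraries also differed in where their counts lay. Of the counts outside mitochondrial DNA, promoter-TSS peaks held 25.2% in the numerator library and 21.7% in the denominator library. Peaks with a log2 CPM of 3 or more held 54.6% and 48.7%. With 1 library per genotype this cannot be assigned to genotype or to library preparation. Its part in the folds by height and class was not tested.

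**Figure D3:**
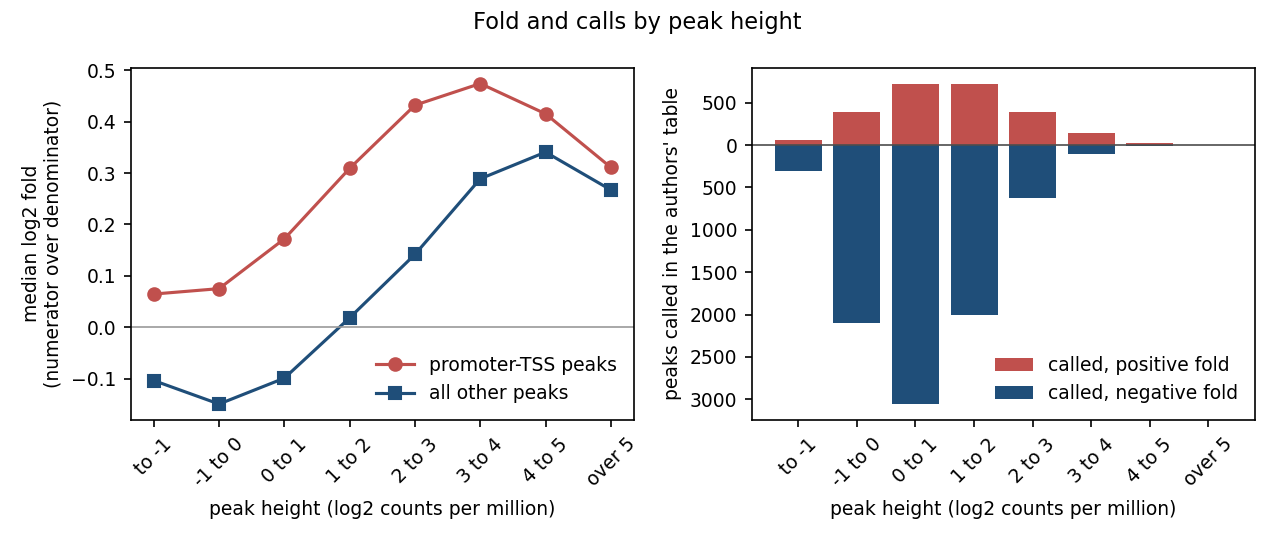
Left, median deposited log2 fold (y axis, numerator over denominator) of promoter-TSS peaks (red circles) and all other peaks (blue squares) in 8 classes of peak height (x axis, log2 CPM). Right, number of peaks called in the authors' deposited table with a positive fold (red, upwards) and a negative fold (blue, downwards) in the same classes; negative calls are most numerous between 0 and 1 (3055).

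Zinc finger genes, which encode DNA-binding repressors and cluster on chromosome 19, led the promoter peaks in both directions. The promoter of ZNF558 (chromosome 19, 8942603 to 8943831) held 18 against 584 counts, a log2 fold of -5.64 (interval -6.42 to -4.98) and an adjusted p of 1.9e-59 in the authors' deposited table. ZNF736, on chromosome 7, had a promoter fold of -6.56, from 1 against 70 counts (interval -12.09 to -4.24). In the opposite direction, the promoter of ZSCAN18 (chromosome 19, 58629575 to 58630076) held 241 against 3 counts (5.65, interval 4.13 to 7.98) and that of ZNF726 held 306 against 6 (5.02, interval 3.90 to 6.50). The promoters of the noncoding genes LINC01535 (-5.10) and LOC654342 (-4.19), of the uncharacterized LOC100128885 (-3.78) and of the pseudogene SEPT7P9 (-4.29) were also among the lowest, and those of FGD5P1 (4.76), ANKRD30B (4.29) and CIDEB (3.58) and the first exon of ZXDA (4.74) among the highest, all folds being those of the authors' deposited table. SEPT7P9 and other pseudogenes have near-identical copies, so their counts are uncertain where reads map to several places.

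Peaks with 0 counts in a library were among the most different. Intergenic peaks nearest to POTEC and CEACAM21 had 39 numerator counts each and 0 denominator counts, at least 8.37-fold higher. The intergenic peak nearest to CEACAM5 was at least 7.51-fold higher, and peaks nearest to CXADRP3, CEACAM18 and RNF17, the last pair in introns, were at least 4.94, 4.94 and 4.51-fold higher. In the other direction, intergenic peaks nearest to LOC101928523, LINC00587, LINC01492, GRIN3A and CYLC2 on chromosome 9 had 24 to 49 denominator counts and 0 numerator counts, between at least 12.4 and at least 25.4-fold lower. An intergenic peak nearest to LINC01899 on chromosome 18 was at least 20.2-fold lower. Peaks nearest to GGT8P (1 against 119 counts, fold -7.33) and upstream of ZNF736 (2 against 182 counts, fold -7.04) completed the lowest 8 in the authors' deposited table.

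Chromosome medians of the deposited fold ran from -0.17 on chromosome 4 to 0.55 on chromosome 19, followed by 0.36 on chromosome 22 and 0.32 on chromosome 17. These 3 chromosomes also had the largest shares of promoter-TSS peaks, 15.7%, 10.2% and 9.54%, but with peaks within 1 kb of a TSS left out chromosome 19 stayed at 0.53. The GC content of the peaks (their share of G and C bases) was not examined, since a genome sequence was not used. Its part in the differences between chromosomes, genomic classes and gene lists was therefore not tested. Random lists were matched on count and not on chromosome. The part of the chromosome differences in the values of single genes and of gene lists was not tested either. Among 300 windows of 10 Mb with at least 100 peaks, the lowest median was -0.40, between 100 and 110 Mb on chromosome 9 (914 peaks). The highest was 0.61, between 0 and 10 Mb on chromosome 19. The lowest window held a run of 74 peaks, delimited after the data were seen, from 104390470 to 106789804, around GRIN3A, LINC00587, CYLC2 and LINC01492, of which 71 were called with a negative fold in the authors' deposited table. Their median fold was -4.44. The run held only 74 of the 914 peaks of the window. Smaller low folds flanked it: the 15 peaks before the run had a median fold of -0.44 and the 15 after it one of -0.75. Whether the flanks share a cause with the run was not tested. Summed over the run, 1100 numerator counts stood against 5045 denominator counts, but the first 15 peaks, up to 104501138, held 850 of these numerator counts. Those 15 peaks had a log2 ratio of -1.75 (interval -1.87 to -1.64) and the other 59 a log2 ratio of -4.31 (interval -4.50 to -4.13).

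**Figure D4:**
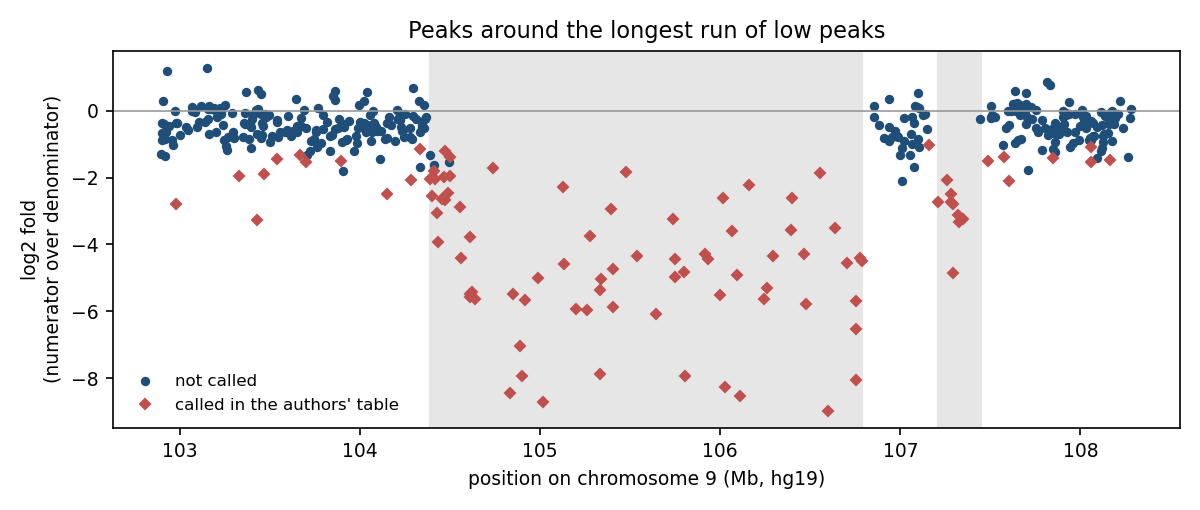
Deposited log2 fold (y axis, numerator over denominator) of peaks against their position on chromosome 9 in Mb (x axis). Grey bands mark 2 runs of low peaks, red diamonds are peaks called in the authors' deposited table and blue circles are other peaks; in the wider band 71 of 74 peaks are called, with a median of -4.44.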

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

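Mitochondrial DNA gave a signal outside the comparisons of peaks on the chromosomes, and this was looked at only after the table was seen. Its 2 peaks held 9.89% of the numerator counts (Wilson interval 9.88 to 9.90) and 18.55% of the denominator counts (interval 18.54 to 18.57). The deposited totals include them. Leaving them out lowered all log2 folds by the same amount, a shift of -0.15. With 1 library per genotype, the shares cannot be assigned to genotype or to nuclei preparation, and neither was tested.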

How the results depend on the processing

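The totals without mitochondrial counts, the larger assumed coefficients of variation, the correction for peak height and class, all rescaled calls, and the list medians without the runs, without peaks near the TSS or without 3 genes were chosen after seeing the data. The 4 scalings shift all folds alike, so by construction they cannot move a list among random lists, and they are left out of the counts of list medians here. The low YAP/TEAD median stayed outside in 11 of 11 other alternatives (excess over random lists -0.32 to -0.15, percentile 0 to 0.3), of which 3 left the list's own median unchanged. The high HOX median stayed outside in 10 of 10 (0.11 to 0.35, percentile 98.3 to 99.99), of which 5 left it unchanged. Of 181 alternative list medians 170 stayed inside or outside the random lists as before, as did 17 of 19 promoter medians. Some of the lists inside moved across the random median, in 12 of 253 alternatives, a count that includes the scalings. The fibroblast list (excess -0.24) came to the bound of the random lists with height and class taken off (-0.15, percentile 2.53) and inside with peaks over 1 kb from the TSS (-0.17). Lists that passed outside were WNT within 10 kb (0.10) and with height and class taken off (0.15), neural ectoderm at any distance (0.13), trophoblast and amnion within 10 kb (-0.14), blood with height and class taken off (0.16), housekeeping by the mean (0.15), cell cycle with at least 50 counts (0.11) and at any distance (0.13), and apoptosis by the mean (0.15). Promoter lists within 2 kb did so for YAP/TEAD (-0.11) and WNT (0.12). The cause was not tested for these lists. Apoptosis also passed the bound without mitochondrial counts (0.13, as in the main values), which is a matter of the random draw alone, since that scaling shifts all folds alike.

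The median over all peaks became -0.025 with median of ratios, -0.033 with TMM, -0.41 with promoter totals, -0.20 without mitochondrial counts, 0.028 with at least 50 counts and -0.11 with pseudocount 5, which by construction lowers ratios to the deeper library. Peaks 2-fold higher numbered 2591 with promoter totals, 4955 without mitochondrial counts, 3887 with at least 50 counts and 3062 with pseudocount 5; 33494 passed 1.5-fold and 401 passed 4-fold. Peaks 2-fold lower numbered 47772 with promoter totals and 9707 with at least 50 counts; 56542 passed 1.5-fold and 1976 passed 4-fold. A p under 0.01 was held by 24052 peaks and an adjusted p under 0.05 by 13165 peaks of the authors' deposited table. Calls with a positive fold numbered 823 with promoter totals, 1448 without mitochondrial counts, 276 at a coefficient of variation of 0.2 and 1 at 0.4, and with a negative fold 23987 with promoter totals, 1706 at 0.2 and 13 at 0.4. YAP/TEAD genes with a negative call numbered 12 to 18 under the scalings and correction, 4 at 0.2 and 0 at 0.4. With height and class taken off, calls numbered 2428 and 7101, of which 1940 and 6605 were shared with the authors' calls.

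The promoter share of higher peaks, below the background by -0.811 points, reversed at 1.5-fold (3.25), 4-fold (0.983) and matched height (1.46). For lower peaks the promoter share stood at -3.34 points at 4-fold and -0.805 at matched height. The exon share stood at 2.502 for higher peaks at 1.5-fold and 7.74 at 4-fold, and for lower peaks at -0.820 at 4-fold and -0.882 at matched height. The YAP1 locus stood at 0.045 without mitochondrial counts. Chromosome 19 stood at 0.53 with peaks over 1 kb from the TSS and 0.58 with median of ratios, and chromosome 4 at -0.19 and -0.15. Except where matching or scaling sets the value by construction, the cause was not tested. Of 96 alternative values of genes named in advance, 35 moved beyond their counting interval.

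The TEAD motif share was not run, since a genome sequence was not used here. Leaving out a replicate was not possible with 1 library per genotype. No paired analysis was possible because the replicate numbers belong to RNA samples whose values were not analysed. In the simulated data, at better-covered peaks, the call, which needs an observed fold of 2 and a fixed coefficient of variation of 0.1, was made for 18% of peaks at a fold of 0.5 and 88% at 0.25. How depth alone changes this was not tested.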

Other observations

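Runs, repeat subfamilies and zinc finger promoters were examined only after the data were seen. Among the tests below, those of the chromosome 9 run and the match of zinc finger promoters on chromosome 19 were chosen after their values were known, while the YAP/TEAD and LTR7 tests were chosen after the low medians were seen, with their bounds written before their own values were computed.

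Repeat subfamilies differed in both directions. Of 319 subfamilies of all classes with at least 60 peaks, 58 lay below and 25 above all of 1000 height-matched random sets each. Endogenous retroviral subfamilies were 172 of the 319, 33 of the 58 and 17 of the 25. Of 79 LINE subfamilies 16 lay below and 5 above, and of 31 SINE subfamilies 8 and 1. The random sets were not matched on genomic class or GC content, and the part of either was not tested. The subfamilies named here were chosen after their values were seen. LTR7, the promoter repeat of the HERVH family that is active in human pluripotent cells, had a median log2 ratio of -0.54 over 771 peaks, against 0.01 in random sets. Of the LTR7 peaks, 113 were called with a negative and 1 with a positive fold in the authors' deposited table. LTR10D (-1.08 over 63 peaks) and MER4D1 (-0.63 over 210) were also low, LTR10A (1.03 over 66) and LTR12C (0.34 over 1536) high. HERVH-int was at -0.13, at percentile 25.8.

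Promoters of zinc finger genes were called more often than other promoters, mostly with a positive fold. Of 549 peaks within 1 kb of the TSS of such genes, 21 were called positive in the authors' deposited table (3.83%, against 1.41% of 21586 such peaks of all genes), above the highest of 1000 height-matched random sets (16). These genes cluster on chromosome 19, the chromosome with the highest median fold. There 5.49% of their promoter peaks and 3.61% of the others were called positive, and elsewhere 2.38% and 1.22%. Random sets also matched on chromosome 19 had a median of 8 and a highest count of 18. Negative calls numbered 3, against a random median of 2. ZNF662 (2.75), ZNF667 (1.58) and ZNF572 (1.78), chosen after their values were seen, were among the positive calls of the authors' deposited table.

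Beside the chromosome 9 run, 8 shorter runs were found. The longest of these with low folds, on chromosome 18 from 68949032 to 70320520, held 17 peaks with a median fold of -3.55. The highest, on chromosome 18 from 14178796 to 15000485 around POTEC and ANKRD30B, held 15 peaks with a median of 3.21.

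The low YAP/TEAD list was weighed first. With the median fold of peaks of like height and class taken off, it stayed at percentile 0 of matched random lists, which argues against the dependence of the fold on peak height and class as the whole cause. With the 3 best-known targets left out it was at percentile 0.07, so ANKRD1, CYR61 and CTGF alone do not account for it. The fibroblast list was also low, and with the same correction its excess over random lists went from -0.24 to -0.15. Whether both lists share a source was not tested. The knockout of YAP1 is the biological explanation that the design gives; it stays open and untested, since the direction of the fold is not given and each genotype has 1 library. A difference between the cultures or library preparations stays open too.

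The chromosome 9 run was weighed next. The test written before the values were known used all 74 peaks, and its dispersion around 1 ratio, 11.4, at percentile 99.5 of 8233 other runs, argued against a loss from part of the cells. The first 15 peaks of the run were less low than the rest, which raises the dispersion whatever the cause, so that test was replaced after its result was seen. The tests given here used the 44 peaks left without the first and last 15, and their bounds were set with the values known. A loss from all cells of the numerator library leaves few counts, but 36.4% of these peaks had more than 3 numerator counts and 15.9% had 0. The cutoff of 3 counts takes no account of peak height. Among the peaks past it, the one at 105404744 held 4 against 156 counts and the one at 104740076 held 16 against 34. How many counts a complete loss leaves was not measured, so this test cannot exclude it. A loss of 1 of 2 copies gives a log2 ratio near -1, and the summed ratio was -4.23 (interval -4.44 to -4.02). A loss from part of the cells gives 1 ratio for all peaks. Around 1 ratio the dispersion of the 44 peaks, 5.67, was at percentile 89.6 of 13868 other runs, and with so few numerator counts this test is too weak to decide. A loss from all or most cells, losses of smaller parts and a regional difference in chromatin may each remain, and genotype was not tested.

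The low LTR7 peaks were weighed last. Reads shared between near-identical copies pull the copies together, yet the interquartile range of their ratios, 0.77, was wide rather than narrow (percentile 98.6 of random sets, whose median was 0.70). A set that mixes copies with and without shared reads can be wide too, and the handling of such reads is not given. Sharing among part of the copies is therefore not excluded. The nearest other peaks within 10 kb were low by -0.18 against their random median. That is 33.4% of the LTR7 difference, between the bounds set for either outcome, so the chromatin around the copies cannot be told apart from the copies themselves. Only peaks named LTR7 were left out of these neighbours, so other repeats of the same elements may be among them. In the same comparison the neighbours of LTR10D and MER4D1 had 11.9% and 13.7% of the repeat's own difference. Those of LTR12C had -13.9% and those of LTR10A 32.0%. The LTR10A ratios were also widely spread, with an interquartile range of 1.60 against a random median of 0.75 (percentile 100). Genotype remains untested, as does a difference in the state of the 2 cultures.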
